A study of Homo sapiens with 8 samples.

How the data were processed

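Sites of 5-hydroxymethylcytosine (5hmC) were mapped by hydroxymethylated DNA immunoprecipitation and sequencing in LX-2 cells. Per the labels' protocols, cells carrying a control or a TET3 overexpression vector were kept in 5 ng/ml TGF-β for 24 h, then fixed with formaldehyde and sonicated. Adapter-ligated fragments were denatured, precipitated with a rabbit antibody against 5hmC and sequenced on a NovaSeq instrument. The 3 control and 3 TET3 libraries each had a deposited peak list, and the 2 input libraries, 1 per group, were not analysed here.

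Per the file headers, the authors called peaks in each library separately and tied each peak to the nearest mRNA, in the classes promoter, gene body and intergenic. The deposited fold enrichment of a peak was read as a linear ratio of its height over a background set by the caller, a meaning inferred from the columns, since the background used is not stated. The background implied by a peak was computed as (height + 1) / fold − 1. The column that the authors headed q-value holds −log10 of the q-value, since its values start near 4 and rise far above 1. The deposited signal at the summit is a whole-number height that is not scaled between libraries. Each of these is the peak's own value in its own list, given by the authors, and was used to describe, rank or filter peaks. The aligner, the peak caller and their versions are not given in the sources used here. In every list the promoter class held peaks whose summit lay within 2000 bp of a transcription start, and peaks tied to several transcripts were counted once. The submitters' processing notes name hg38. The peaks on chromosome 1 reach position 249239716, past the last gene of GRCh38, and 15.1% of 15952 compared genes overlap their GRCh38 position, so the build is left unnamed and coordinates are printed as the files give them. Gene symbols are those of the files, and 17071 of the 17121 gene numbers behind them were matched to a RefSeq table of GRCh38, used for names and for the density of genes per chromosome. Total reads per library are not in the peak lists, so depth is unknown, and a peak that is missing from a list was not called, which does not show that 5hmC was absent.

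Groups were taken from the labels. Peak number, covered length and the promoter share were compared by a two-sided exact permutation test of 3 against 3 libraries, whose smallest p is 0.1. Similarity was the Jaccard index of covered base pairs, compared over the 10 splits of the 6 libraries. Peaks of all libraries that overlapped by at least 1 bp were merged into regions with bedtools 2.31.1. A region or a gene's promoter was called TET3-only when it had a peak in 3 of 3 TET3 and 0 of 3 control libraries, and control-only in the opposite case. For genes, the covered base pairs of all peaks tied to a gene, per Mb of the library's covered length, were tested as log2(value + 10) with limma 3.58.1 (trend and robust options, R 4.3.3) in the 14645 genes with a peak in at least 3 libraries. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on this scale understate the change of genes with little covered length, and those of genes with no peak in a whole group depend on the added constant, so covered lengths are given for them instead. The 21 gene lists were fixed before the data were examined. Their 643 genes, 609 of them found in the files, cover matrix, stellate cell activation and quiescence, TGF-β, PI3K, WNT, Hippo, Hedgehog and Notch, FOXO and apoptosis, inflammation, matrix degradation, integrins, cell cycle, DNA methylation, chromatin, HOX and housekeeping genes, and markers of hepatocytes, cholangiocytes, endothelium and leukocytes. They were tested with camera (inter-gene correlation 0.01, and again with an estimated correlation) and by Fisher's exact test of TET3-only against control-only promoter genes. Python 3.11.15 with SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 served for the rest.

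Genes were named by a rule set before the data were examined. It took TET3 itself, the 10 TET3-only and 10 control-only promoter genes whose promoter peaks ranked highest by fold within their libraries, and the 10 genes with the largest log2 fold change in each direction past the limma threshold. From each list it took at most 4 TET3-only or control-only promoter members and the 2 members with the smallest limma p. Uncharacterised loci were skipped. Other list members that passed a threshold, and HOXB7, HOXC13 and HOXD10, are also named, chosen after their values were seen.

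Alternatives set before the data were examined were a stricter peak threshold (a −log10 q-value of at least 21.2, the median of all lists), the 55118 strongest peaks of every library, each library left out in turn, a reciprocal overlap of 50%, a window of 2 kb around starts, a replicate block, added constants of 2 and 50, no gene filter, a filter on all 6 libraries, peak number per gene (added constant 0.2 per 10000 peaks) and no scaling (added constant 300 bp). A minimum fold of 10 and the removal of promoter peaks from the gene-level test were added after the data were seen, as were a Fisher's exact test of each list against all genes named in the files and a test of 26 keywords in protein names.

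The gene-level test was tested on simulated data made from the 14645 genes of this comparison. It recovered 7 of 100 genes changed by 1 log2 unit and 43 of 100 changed by 2, with 0 false calls, and called 0 genes when no change was simulated. The region counts returned all 200 TET3-only and 100 control-only regions planted beside 20000 peaks. The planted peaks lay apart on a simulated chromosome, so this checked the counting only and not how often such regions arise falsely. In the gene-level simulations false calls were rare and many planted changes were missed. Simulated values varied independently between genes, with no effect shared by a library and no floor for absent peaks. The rate of false calls in the real data was therefore not tested.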

Results

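Hydroxymethylation of DNA was profiled in LX-2, an established line of human hepatic stellate cells, the cells that deposit matrix in the fibrotic liver. All cultures received 5 ng/ml TGF-β, the cytokine that activates stellate cells, for 24 h. Peaks of 5hmC, the oxidised form of 5-methylcytosine, were compared between 3 libraries from cells with a control vector and 3 from cells that overexpressed TET3, an enzyme that makes 5hmC. The design asks which hydroxymethylated regions differ between the groups. The lists held 57689, 79323 and 55118 peaks in control replicates 1, 2 and 3 and 56579, 62762 and 57624 in TET3 replicates 1, 2 and 3. The reads behind each list are unknown, so depth is unknown. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No test of 3 against 3 libraries can give an exact permutation p under 0.1.

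Peaks tied to the TET3 gene itself covered 1786, 3009 and 1300 bp in control replicates 1, 2 and 3, and 1991, 1516 and 2842 bp in the TET3 replicates. The difference lay within the spread between libraries (log2 fold change 0.10, SE 0.30, limma adjusted p = 0.877), and its sign turned without control replicate 3 (−0.04) and without TET3 replicate 3 (−0.12). A region upstream of the start, on chromosome 2 from 74211090 to 74211940, was called in 2 of 3 control and 3 of 3 TET3 libraries. Its peaks had a fold enrichment, as the authors' caller gave it, of 7.41 ± 0.882 (SD, n = 2) and 13.6 ± 2.36 (SD, n = 3). A region in the gene body, from 74292427 to 74293174, was called in all 6 libraries, at 18.1 ± 6.58 in control and 15.3 ± 2.02 in TET3 libraries (SD, n = 3 each). Peaks of 5hmC on the gene do not measure its expression, so they do not check the labels of the overexpression.

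5hmC peaks lay at gene promoters more often in TET3-overexpressing cells. Promoters took 8.40% ± 1.22 of the peaks there and 3.99% ± 0.915 in control cells (SD, n = 3 each), a 2.10-fold difference. The 3 TET3 libraries, at 9.80%, 7.55% and 7.85%, all lay above the 3 control libraries, at 3.83%, 4.98% and 3.17% (exact permutation p = 0.1, two-sided). The share of intergenic peaks was lower, at 61.4% ± 1.92 against 66.7% ± 1.90 (exact permutation p = 0.1), and gene bodies took 30.2% ± 0.728 and 29.3% ± 0.996 (exact permutation p = 0.4). Promoter peaks were found at 4175 ± 372 genes per TET3 library and 2371 ± 952 genes per control library (exact permutation p = 0.1).

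**Figure D1:**
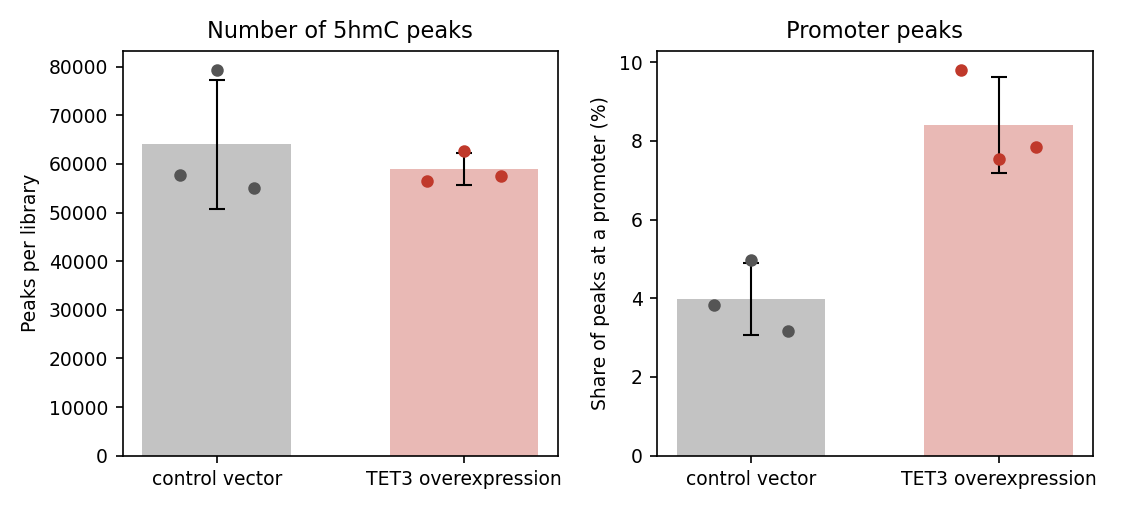
Number of 5hmC peaks (left) and percentage of peaks at a promoter (right) in 3 control-vector and 3 TET3 libraries, as means with SD and single libraries as points. The promoter share of every TET3 library, from 7.55% to 9.80%, lies above that of every control library, from 3.17% to 4.98%, while peak numbers overlap.

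The excess was steepest next to the transcription start and turned into a deficit far from any start. Peaks with a summit within 500 bp of a start made up 2.05% ± 0.368 of the TET3 lists and 0.794% ± 0.227 of the control lists, 2.58-fold more. The ratio was 2.41 from 500 to 1000 bp, 1.74 from 1000 to 2000 bp and 1.23 from 2000 to 5000 bp. Beyond 100 kb the share was 28.4% ± 2.78 in TET3 and 35.3% ± 2.52 in control libraries, a ratio of 0.807. All 3 libraries of each group lay on the same side in each of these bins (exact permutation p = 0.1 each).

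**Figure D2:**
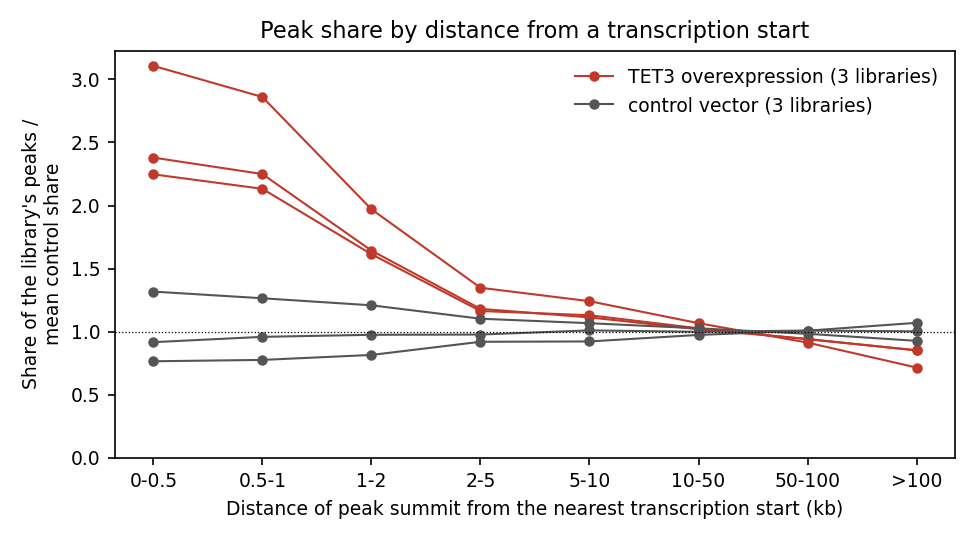
Share of each library's peaks by distance of the summit from the nearest transcription start (kb), divided by the mean control share, for 6 single libraries. The mean ratio of TET3 to control runs from 2.58 within 500 bp of a start to 0.807 beyond 100 kb.

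The number and covered length of called peaks did not separate the groups. With depth unknown, these values do not measure how much DNA was hydroxymethylated, so a change in that amount was not tested. TET3 libraries held 58988 ± 3310 peaks over 43.0 ± 1.89 Mb and control libraries 64043 ± 13295 peaks over 44.2 ± 9.69 Mb (exact permutation p = 0.8 and 1). Both differences rest on control replicate 2, without which TET3 libraries held 2585 more peaks and 4.38 Mb more covered length. Where the peaks lay differed more between than within the groups on average: libraries of the same group shared a mean Jaccard index of 0.400 and libraries of different groups 0.329 (exact permutation p = 0.1 over 10 splits). The TET3 pairs carried this, at a mean of 0.452, while control pairs had a mean of 0.347. The difference of 0.0701 fell to 0.0378, 0.0465 and 0.0466 without TET3 replicates 1, 2 and 3. It rose to 0.0933, 0.109 and 0.0879 without control replicates 1, 2 and 3. Control replicates 2 and 3 shared 0.311, less than control replicate 2 shared with TET3 replicates 1, 2 and 3 (0.338, 0.343 and 0.332), and control replicate 1 shared almost as much with TET3 replicate 3 (0.350) as with control replicate 2 (0.351).

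TET3 libraries had the lower background in their peak lists. The background implied by height and fold had a median of 3.405 ± 0.0604 in TET3 and 3.99 ± 0.00681 in control libraries (SD, n = 3 each, exact permutation p = 0.1). The median fold was 7.97 ± 0.267 in TET3 and 7.19 ± 0.230 in control libraries (exact permutation p = 0.1). TET3-only counts, and folds set side by side between the groups, can carry part of this difference.

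Promoters set the TET3-only regions apart from the control-only regions, although most regions of either kind lay elsewhere. Of 146877 merged regions, 17375 had a peak in all 6 libraries, 3479 were TET3-only and 2040 control-only. Promoter regions numbered 907 among the TET3-only and 43 among the control-only regions, 26.1% and 2.11% of them. Gene bodies held 961 and 625 and intergenic DNA 1611 and 1372. The other 9 splits of the libraries gave at most 1314 regions in either direction. The TET3-only count rose to 6594 without control replicate 2, and to 5338, 5579 and 5899 without TET3 replicates 1, 2 and 3. The control-only count rose to 4711, 4241 and 5178 without control replicates 1, 2 and 3, and to 3067 without TET3 replicate 2; a region has to meet fewer conditions when a library is left out.

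**Figure D3:**
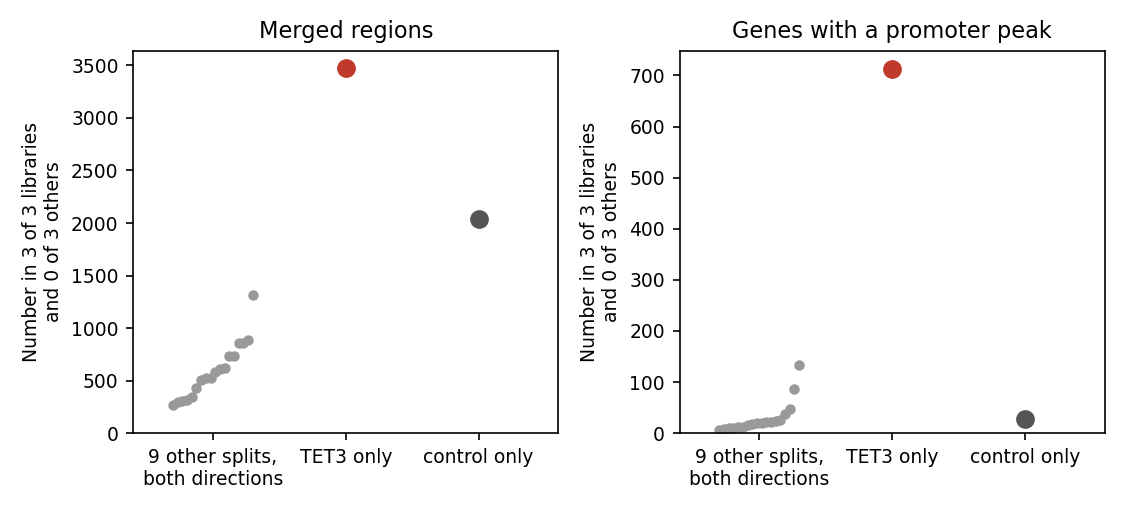
Merged regions (left) and genes with a promoter peak (right) that were present in 3 of 3 libraries on one side of a split and 0 of 3 on the other, with the other 9 splits as small points. The TET3-only points, 3479 regions and 713 genes, lie above all other splits, and the control-only point for genes, 27, does not.

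Promoter peaks at 713 genes were TET3-only and at 27 genes control-only. The TET3-only promoters with the highest ranking folds belonged to genes of varied function. RNF208, a RING finger protein, had a peak of fold 28.2 ± 4.39 (SD, n = 3) on chromosome 9 between 140114719 and 140116437. MSLN, the surface protein mesothelin, had one of 25.2 ± 7.44 on chromosome 16 between 809668 and 811679. The others were the fatty acid hydroxylase CYP4F2 (28.1 ± 3.14), the ribosomal protein RPS15A (27.2 ± 7.90), the Golgi protein GOLPH3 (24.4 ± 2.47), complement component C2 (27.4 ± 13.2), the sugar transporter SLC45A1 (22.5 ± 5.40), the interleukin-17 receptor IL17RA (19.8 ± 4.16), the semaphorin SEMA6C (18.9 ± 1.71) and GATSL2 (29.2 ± 5.67). GATSL2, CYP4F2 and RPS15A have close paralogs or pseudogenes, so reads at them are uncertain. The CYP4F2 and GOLPH3 summits, at medians of 1986 and −1965 bp, lay at the edge of the promoter class. Covered length of CYP4F2 was 2.89 ± 0.157 kb in control and 2.905 ± 0.0244 kb in TET3 libraries (SD, n = 3 each, limma adjusted p = 0.974). That of GOLPH3 did not pass the threshold either (log2 fold change 0.314, limma adjusted p = 0.438).

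The control-only promoters were fewer. They included RARB, the retinoic acid receptor β (fold 9.74 ± 2.74, SD, n = 3, chromosome 3 between 25500927 and 25502317), and SERPINA6, the corticosteroid-binding globulin (9.08 ± 1.80). ACSL3, which activates long-chain fatty acids, had 10.6 ± 1.93, UAP1, which makes UDP-N-acetylglucosamine, 13.3 ± 7.45, and HGS, a sorting protein of endosomes, 11.02 ± 4.81. AGTPBP1 (14.1 ± 3.42), ASMT (13.4 ± 4.15), TMTC1 (11.8 ± 1.20), FXYD2 (15.4 ± 12.01) and MARCH10 (11.9 ± 7.25) completed the 10. The ASMT summit, at a median of −1957 bp, lay at the edge of the promoter class. Covered length of that gene was 22.8 ± 4.87 kb in control and 20.6 ± 2.01 kb in TET3 libraries. Of 7033 genes with a promoter peak in any library, 4260 had it in more TET3 than control libraries, 1349 in more control libraries, and 805 in all 6. The other splits gave at most 134 genes on a side. Without control replicate 2 the TET3-only count was 1228. The control-only count was 85, 52 and 102 without control replicates 1, 2 and 3 and 46, 51 and 47 without TET3 replicates 1, 2 and 3.

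Genes of fibrosis pathways were among the TET3-only promoters, each in small number. Over all genes, 4260 had promoter peaks in more TET3 and 1349 in more control libraries, and the list numbers here were not tested against that tilt. Of all genes named in the files 4.16% were TET3-only. No list given here differed from that share (Fisher's exact test added after the data were seen, adjusted p from 0.835 to 0.868). Of the 37 TGF-β and SMAD genes found, 15 had promoter peaks in more TET3 and 3 in more control libraries; LTBP1, which anchors latent TGF-β, ID1, a SMAD target, and SMAD9 were TET3-only. ID1 had a peak of fold 10.5 ± 1.98 (SD, n = 3) upstream of its start on chromosome 20, between 30190992 and 30192146. Among 32 matrix genes, 9 had more TET3 and 3 more control libraries, with FBN1 (fibrillin) and COL6A2 TET3-only. Of the pro-apoptotic genes, BCL2L11 (BIM, a FOXO target) had a peak of 9.56 ± 2.11 on chromosome 2 between 111877721 and 111879976, and BID one of 7.84 ± 0.974. The FOXO and apoptosis list had 11 genes with more TET3 and 4 with more control libraries. None of the 29 stellate activation genes, the 25 quiescence genes, the 25 DNA methylation genes or the 36 chromatin regulators was TET3-only or control-only. With so few genes per list, having no TET3-only gene does not set a list apart (adjusted p = 0.868 in each by the same Fisher's exact test).

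Promoters of signalling and cell cycle genes also gained peaks in single TET3-only cases. Over all genes the tilt was 4260 with more TET3 and 1349 with more control libraries, and the list numbers below were not tested against it. In the WNT list 18 genes had more TET3 and 3 more control libraries, and the WNT antagonist SFRP1, the scaffold AXIN1 and the transcription factors TCF7 and LEF1 were TET3-only. In the Hedgehog and Notch list the numbers were 12 and 0, with NOTCH1 and its nuclear partner RBPJ TET3-only. The cell cycle list had 14 and 1, with PLK1, CDC20, cyclin D2 (CCND2) and the inhibitor CDKN2A TET3-only. INSR and IRS1 of the PI3K list (11 and 1), TEAD3 of the Hippo list (8 and 1), IRF1 of the inflammation list (14 and 3), MMP11 of the matrix degradation list (9 and 4), and PARVA and CRK of the integrin list (11 and 3) were TET3-only. So were MUC1 of the cholangiocyte markers (4 and 4), STAB1 of the endothelial markers (5 and 1) and ACTB of the housekeeping genes (7 and 1). Hepatocyte markers (2 and 1) and leukocyte markers (4 and 2) had no gene of either kind. No list held a control-only promoter gene, and the balance of TET3-only to control-only genes differed from that of other genes in 0 of the 15 lists tested (Fisher's exact test, adjusted p = 1 in each). With 27 control-only genes in all, that test had little room to show a difference.

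HOX genes, the clustered regulators of body position, gained promoter peaks most often among the lists. Of the 30 HOX genes found, 18 had promoter peaks in more TET3 and 2 in more control libraries, and 7 were TET3-only: HOXA11, HOXB7, HOXC4, HOXC6, HOXC11, HOXC13 and HOXD10. That is 23.3%, against 4.16% of all genes named in the files (Fisher's exact test, p = 0.0001856, adjusted p = 0.00390 over 21 lists, a test added after the data were seen). No other list passed it (adjusted p from 0.649 to 1). The test counted neighbouring HOX genes as independent, so its p-value for them may be too small. In the HOXC cluster on chromosome 12, between 54327575 and 54454814, TET3 libraries had 14, 10 and 9 peaks and control libraries 5, 4 and 2 (exact permutation p = 0.1). The HOXC11 start had a peak of fold 9.45 ± 2.18 (SD, n = 3) between 54366912 and 54367842, and the HOXC13 start one of 9.001 ± 3.08 between 54332375 and 54333576. HOXC4 and HOXC6 share a region near 54411813, since a transcript of HOXC4 starts there.

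**Figure D4:**
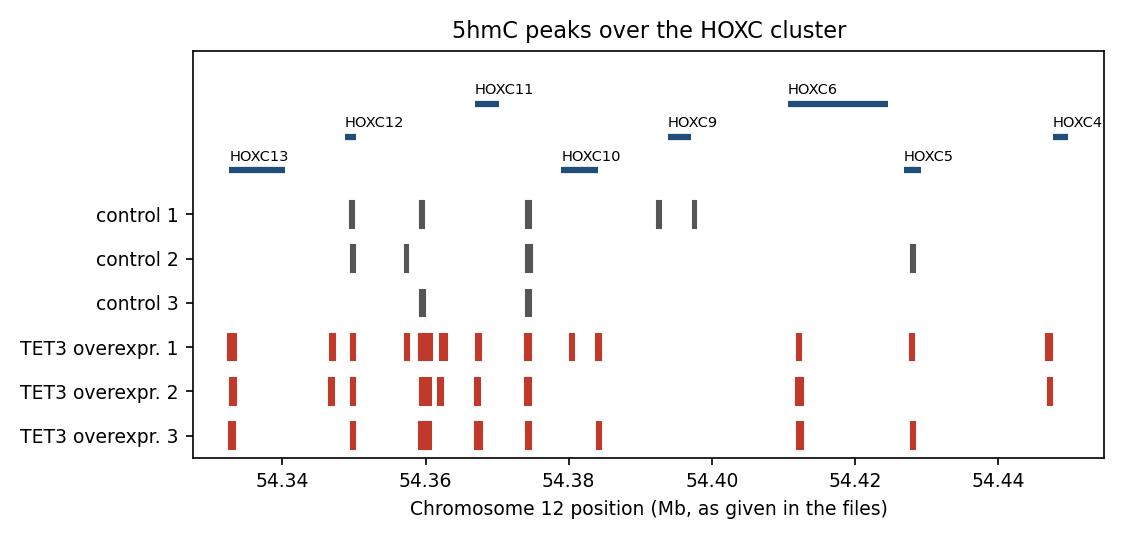
Peaks of 5hmC over the HOXC cluster on chromosome 12, with genes above and peaks of the 6 libraries in lanes below (positions in Mb, as the files give them). TET3 libraries have 14, 10 and 9 peaks in the window and control libraries 5, 4 and 2, with peaks at the HOXC13, HOXC11 and HOXC6 starts in the TET3 lanes alone.

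Covered length per gene summed every peak tied to it as the nearest mRNA, intergenic peaks included, so it can lie outside the gene. By this measure 340 genes had more covered length in TET3 libraries and 111 had less (limma adjusted p under 0.05 of 14645 genes). TSC2, a brake on mTOR, had no peak in any control library and 3.22 ± 0.333 kb in TET3 libraries (SD, n = 3; adjusted p = 0.0303). The growth factor receptor FGFR3 (3.38 ± 1.76 kb) and SMIM5 (3.07 ± 0.783 kb) likewise had none in control libraries. The G-protein subunit GNG13 had 3.74 ± 0.409 kb against 0.221 ± 0.382 kb, the organic anion transporter SLCO4A1 3.72 ± 0.865 against 0.262 ± 0.454 kb, and GAMT, an enzyme of creatine synthesis, 3.39 ± 1.34 against 0.171 ± 0.296 kb. TMEM120A, SAP25 and TAS1R3 followed, with log2 fold changes of 2.88, 2.81 and 2.76.

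The genes with the most negative log2 fold changes had peaks in the control libraries and none, or almost none, in TET3 libraries. Other called genes lost more covered length and kept peaks, such as ARID1B (16.6 ± 4.13 kb in control and 9.79 ± 0.881 kb in TET3 libraries). They included LRRC28 (2.36 ± 1.17 kb in control libraries, SD, n = 3), GBP5, an interferon-induced GTPase (2.12 ± 0.491 kb), the bicarbonate transporter SLC4A10 (2.03 ± 0.787 kb), GPRC6A (1.62 ± 0.576 kb), FAM9C (1.64 ± 0.782 kb), the mRNA cap methyltransferase RNMT (1.53 ± 0.325 kb), ZNF780A (1.54 ± 0.403 kb) and the T cell cytokine gene IL2 (1.54 ± 0.464 kb), all listed at 0 in the TET3 libraries. The olfactory receptor OR11H12 had 2.39 ± 0.719 kb in control and 0.166 ± 0.288 kb in TET3 libraries. Of the 340 genes that gained, 100 were TET3-only promoter genes and 276 had a promoter peak in some library, while of the 111 that lost 1 was a control-only promoter gene (the laminin chain LAMA2, chosen after its value was seen) and 20 had a promoter peak in some library. With promoter peaks taken out, an alternative added after the data were seen, 99 genes were higher and 31 lower. Both counts fell to 0 without control replicate 1, without control replicate 3 and without each TET3 replicate, and were 474 and 60 without control replicate 2; they were 0 with equal peak numbers, with peak number per gene, without scaling and with an added constant of 2. In those of these settings with counts of 0, 1112 to 1887 genes were higher and 920 to 1353 lower at an unadjusted p under 0.05.

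Matrix and stellate cell genes went both ways. Of 31 matrix genes tested, COL5A1 (31.4 ± 2.96 against 17.0 ± 5.61 kb, SD, n = 3 each, log2 fold change 0.93, limma adjusted p = 0.0342) and the basement membrane collagen COL4A1 (1.02, adjusted p = 0.0389) rose and none fell. Adjustment over the list alone, here and below, does not correct for the number of lists. Among all 14645 genes tested, 2017 were higher and 1381 lower at an unadjusted limma p under 0.05. The counts within lists were not tested against these numbers, so they do not set a list apart from other genes. Adjusted over the list alone, 4 matrix genes were higher and 3 lower, the latter COL8A1, CYR61 and the fibrillar collagen COL3A1 (−1.05, adjusted p = 0.0961 over all genes). Of 28 stellate activation genes, the collagen chaperone SERPINH1 (1.18, adjusted p = 0.0403) and the myosin light chain MYL9 (2.41, adjusted p = 0.0446) rose. Adjusted over the list alone, 3 were higher, TIMP2 included, and 1 was lower: ACTA2, the smooth muscle actin that marks activated stellate cells, had 0.564 ± 0.533 kb in TET3 and 2.68 ± 1.29 kb in control libraries (adjusted p = 0.0762 over all genes). Of 23 quiescence genes the retinoid receptor RXRA rose (1.05, adjusted p = 0.0342); adjusted over the list alone, 2 were higher, RXRA and GFAP (2.01).

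In the TGF-β list of 36 tested genes, ID1 rose (10.99 ± 2.16 against 3.64 ± 1.99 kb, SD, n = 3 each, log2 fold change 1.62, limma adjusted p = 0.0358). Adjusted over the list alone, 5 were higher, the inhibitory SMAD7 and SMAD6 among them, and 2 were lower, TGFB2 (−1.06, adjusted p = 0.0573 over all genes) and BMPR1B. Of 33 PI3K and PDGF genes, TSC2, PDPK1 (1.92, adjusted p = 0.0391) and PIK3R2 (2.30, adjusted p = 0.0419) rose and the growth factor PDGFC fell (−1.07, adjusted p = 0.0355); adjusted over the list alone, 5 were higher and 1 lower. Of 30 cell cycle genes, E2F1 (2.36, adjusted p = 0.0389), AURKB (2.24, adjusted p = 0.0436) and cyclin D1 (CCND1, 0.64, adjusted p = 0.0440) rose; adjusted over the list alone, 8 were higher and 4 lower, the proliferation marker MKI67, CDK1, CCNB1 and E2F7. GLI2, a Hedgehog effector, rose (1.10, adjusted p = 0.0359) among 24 Hedgehog and Notch genes; adjusted over the list alone, 6 were higher and 3 lower, the inhibitor HHIP and GLI3 among the latter.

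The other lists held few calls. WNT7B rose (log2 fold change 0.93, limma adjusted p = 0.0350) among 43 WNT genes, 3 being higher and 0 lower adjusted over the list alone (WNT7B, LRP5 and AXIN1). VGLL3, a cofactor of TEAD factors, fell (−1.04, adjusted p = 0.0451) among 25 Hippo genes, with 2 higher (TEAD4 and AMOTL2) and 4 lower adjusted over the list alone. The adhesion scaffold PXN rose (0.84, adjusted p = 0.0426) among 34 integrin genes, with 4 higher (PXN, CRK, ZYX and PTK2) adjusted over the list alone. PTK2 turned to −0.10 with the stricter peak threshold. The chromatin remodeller ARID1B fell (−0.69, adjusted p = 0.0459) among 33 chromatin regulators, and was also the only gene past the threshold adjusted over the list alone. STAB1 rose (2.40, adjusted p = 0.0342) among 18 endothelial markers; adjusted over the list alone 1 was higher and 1, EMCN, lower. No gene passed over all genes among 24 DNA methylation genes (DNMT3L 1.64, adjusted p = 0.0690; MBD2 −0.60, adjusted p = 0.0930), 31 FOXO and apoptosis genes (BCL2L11 0.55, adjusted p = 0.109; BID 0.91, adjusted p = 0.153), 18 hepatocyte markers (CYP2E1 −1.22, TAT −1.23), 15 cholangiocyte markers (MUC1 0.97, CLDN4 1.58) and 16 leukocyte markers (VSIG4 −1.25, PTPRC −0.78), nor adjusted over the list alone. Nor did any of 36 inflammation genes, 35 matrix degradation genes or 16 housekeeping genes pass over all genes. Adjusted over the list alone, IL6R was higher and IL6 lower, TIMP2 was higher and MMP16 and MMP2 lower, and RPLP0 was higher.

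As a set, the HOX genes were the only list of 21 past the threshold, a call that depended on the preset correlation of 0.01. The median log2 fold change of 21 tested HOX genes was 0.98, with 18 positive (camera adjusted p = 0.000152). The call was lost at adjusted p = 0.842 with an estimated correlation. It was also lost with promoter peaks taken out (adjusted p = 0.410), where 9 HOX genes could be tested and their median log2 fold change was 0.46, so fewer members may be part of that loss. No HOX gene passed over all genes (HOXA11 adjusted p = 0.0541, HOXC11 0.0544), and 11 were higher adjusted over the list alone. The other lists had camera adjusted p from 0.515 to 0.990, and from 0.842 to 0.989 with an estimated correlation. Median, mean and test differed in sign for the chromatin list (median −0.04, mean 0.06, tested as down), the Hippo list (0.08, −0.06, down) and the matrix degradation list (0.04, −0.10, down).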

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

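The minimum fold of 10 and the removal of promoter peaks were chosen only after the results were seen. The higher promoter share of peaks in TET3 libraries kept its direction in every alternative tried, with a difference of 4.43 percentage points under the stricter peak threshold, 4.35 with equal peak numbers, 4.66 with a window of 2 kb, 4.07 at a fold of 10 or more, and 3.71 to 4.90 with each library left out. Same-numbered libraries did not deviate together (correlations −0.00888, −0.0489 and 0.117), so the numbers do not pair them. With a replicate block, the promoter difference was 4.41 points (exact sign-flip permutation p = 0.25, the smallest possible), and the limma counts of genes higher in TET3 and genes lower in TET3 were 0 and 0, with 1980 and 1420 genes at an unadjusted p under 0.05. Peaks per library turned from −5055 to 2008 at a fold of 10 or more and ranged from −9518 to 2585 with each library left out. Covered length per library turned from −1.17 Mb to 0.517 Mb (stricter threshold), 1.45 Mb (equal numbers) and 2.31 Mb (fold of 10 or more), and ranged from −4.55 to 4.38 Mb with each library left out; the cause was not tested. The stricter threshold and the fold of 10 or more keep fewer peaks by construction: TET3-only regions numbered 1835 and 1541, control-only regions 1134 and 692, and TET3-only promoter genes 396 and 282, and control-only promoter genes numbered 15 at a fold of 10 or more. With a library left out the ranges were 3990 to 6594, 2792 to 5178, 746 to 1228 and 46 to 102, in the same order. Genes higher and lower in TET3 by limma were 7 and 1 under the stricter threshold, 0 and 0 with equal numbers, an added constant of 2, peak number per gene and no scaling, 618 and 227 with an added constant of 50, 99 and 31 without promoter peaks, and 0 to 474 and 0 to 60 with each library left out; the settings with counts of 0 had smallest adjusted p from 0.0533 to 0.154, and all 451 called genes that could be tested kept their direction except 2 of 386 under the stricter threshold. The called genes were picked for their differences in these same libraries. Their kept direction was therefore largely fixed in advance and lends the calls no support. At an unadjusted p under 0.05 the main counts were 2017 and 1381. Of the gene lists, 0 passed under the stricter threshold, the filter on all 6 libraries, the estimated correlation and without promoter peaks, against 1 otherwise. The TET3 log2 fold change was −0.0472 under the stricter threshold and −0.12 to 0.31 with each library left out, including −0.04 without control replicate 3; VSIG4 turned to 0.0515 and PTK2 to −0.10 under the stricter threshold. No other named gene changed sign: of 1631 values for 111 genes in the gene-level test, 5 were reversed, 396 weaker, 67 stronger and 1163 the same, all 396 losses falling on the 39 called genes, of whose 551 values 155 kept the call, and of 156 values for 52 promoter genes, 117 kept the pattern. Unknown depth limits all counts of absent peaks.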

Other observations

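The keyword, chromosome and list enrichment tests, the test of gene-dense chromosomes and the counts over other splits were chosen only after the result was seen, equal peak numbers were a planned setting whose use against an explanation was chosen after its value was seen, and the tests of summit height and of the HOX genes were set before their own results. Groups of genes outside the fixed lists also differed. Olfactory receptor genes, which are silent in most tissues, held 0 TET3-only promoters among 239 genes, against 4.16% of all genes (Fisher's exact test, p = 5.845e-05, adjusted p = 0.00152 over 26 keywords). Genes with the word phosphatase in their protein name held more, 22 of 275 or 8.00% (adjusted p = 0.0435). Genes with histone in the protein name, not all of them histones, held 11 of 114 or 9.65% (adjusted p = 0.0691). Those with zinc finger in the name held 18 of 671 or 2.68% (adjusted p = 0.315), and neither keyword passed the threshold.

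Peaks were also spread differently over the chromosomes. In TET3 libraries chromosome 22 held 1.33, chromosome 17 held 1.32, chromosome 19 held 1.302 and chromosome 16 held 1.20 times its control share of peaks, with all 3 TET3 libraries above all 3 control libraries (exact permutation p = 0.1 each). Chromosome 4 held 0.836, chromosome X 0.842, chromosome 13 0.847 and chromosome 18 0.869 times its control share (exact permutation p = 0.1 each).

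The excess of promoter peaks in TET3 libraries was weighed against 3 technical explanations. Unequal peak numbers are argued against as the whole cause, since the difference stayed at 4.35 percentage points (larger SD 1.23) with equal numbers, and so is the lower background of the caller in TET3 libraries, since among 17375 regions called in all 6 libraries the 913 promoter regions ranked 9.156 percentiles higher by summit height in TET3 libraries (56.2 ± 1.85 against 47.1 ± 2.92, SD, n = 3 each). A shift of all peaks towards gene-dense chromosomes stays open as a part of the excess. Even peaks over 100 kb from a start lay more often on the 5 densest chromosomes in TET3 libraries, by 0.9244 points (10.4% ± 0.638 against 9.52% ± 0.207). As the whole cause it is argued against, since the promoter share also rose within each set of chromosomes. From control to TET3 libraries that share went from 3.20% ± 0.765 to 7.04% ± 1.15 on the other chromosomes. On the dense ones it went from 7.96% ± 1.36 to 13.8% ± 1.06 (SD, n = 3 each). A preference of the TET3 libraries for GC-rich or open DNA could give all of these values and could not be checked without the genome sequence, and the single input per group is a further open point.

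The frequent gain of promoter peaks at HOX genes was weighed against 2 explanations. Neighbouring genes that share a region do not account for it alone: with 1 gene kept per merged region, 6 HOX genes on 4 chromosomes were left and Fisher's exact p was 0.001016. It did not extend to homeobox genes as a class, of which 5 of 137 outside the clusters (3.65%, 95% exact binomial interval 1.20 to 8.31, covering counting error only) were TET3-only, against 23.3% (9.93 to 42.3) of HOX genes (Fisher's exact p = 1 against other genes). The Fisher's exact tests counted neighbouring HOX genes with separate peaks as independent, so the p-values for HOX genes may be too small. With an estimated inter-gene correlation the camera call for HOX genes was lost (adjusted p = 0.842). HOX clusters are rich in CpG islands, so the GC preference named for promoters could also act here and is open.

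Chance in the grouping of the libraries cannot be judged from 10 splits, which never give a share under 0.05. The real split gave 3479 TET3-only and 2040 control-only regions, against at most 1314 in the others, so 1 of 10 splits reached either count. It gave 713 TET3-only promoter genes, against at most 134, with 1 split as large, and 27 control-only promoter genes, which 5 of 10 splits reached. It gave 340 genes higher and 111 lower by limma, against 0 in each other split, with 1 split as large. It gave 1 gene list, which 4 of 10 splits reached, with 5 lists as the highest other.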
